A study of Mus musculus with 56 samples.

How the data were processed

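The samples were mouse embryonic stem cell cultures turned into spinal progenitors, with libraries of RNA and of chromatin immunoprecipitation (ChIP) from day 4 and of H3K27ac from day 6. Groups came from the sample labels alone: pMN (no induced factor), iNkx2.2 and iTNmut (1 µg/mL doxycycline for 14 to 16 h), and day 6 motor neurons. Per the labels' protocols, chromatin was fixed with 1% formaldehyde, after 2 mM disuccinimidyl glutarate for HDAC2 and Grg. The RNA pMN libraries came from the uninduced iNkx2.2 line, whereas the ChIP pMN libraries came from parental lines (HBG3 for replicate 1 and A2lox.Cre for replicate 2 of p300, H3K27ac and H3K4me1, A2lox.Cre for HDAC2, Grg and H3K27me3, HBG3 for Med1). iTNmut was another line, and pMN had no doxycycline. The Sox2 pMN library came from another study, per the labels. An input library named in the labels was not analysed here. The labels do not say that replicates were separate cultures, so p-values measure the spread between samples.

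The authors aligned reads to mm10 with STAR for RNA and Bowtie 0.12.7 for ChIP, per the submitters' processing notes, which also name Cufflinks, bedtools 2.17.0, edgeR 3.20.9 and limma 3.34.9. The deposited RNA and ChIP tables hold raw counts per gene or region, and these counts were the input of every main test. The authors' FPKM values for RNA, made with Cufflinks per the submitters' processing notes, and the authors' log2 CPM and log2 fold change columns served only alternatives and comparison. The authors' score of -1, 0 or 1 per gene, deposited with the significant genes of RNA, was compared with the calls made here, and such tables for ChIP were not used here. Per the file headers, the day 6 peak lists hold MACS 2.0.9 broad regions called against whole-cell extract at q 0.01, with the signal (pileup) and the ratio (fold enrichment) of each region, of which only the positions were used. HDAC2 peak lists and GEM event files were not used here. The names of the HDAC2 peak lists give another state or replicate than the sample labels do in 2 of 3 cases, and the HDAC2 libraries were assigned by the column names of the count table. How strand was treated in counting is not stated, nor is the width of the window in which reads at point sites were counted.

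Count tables were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, the data.table package (1.17.8), jsonlite 2.0.0 and GenomicRanges 1.54.1. Genes or regions were kept by filterByExpr (15388 of 39017 genes, 30105 of 30107 p300 regions and all regions of the other tables), scaled by TMM, and tested with edgeR quasi-likelihood F tests in a single fit of all groups without a block. Benjamini-Hochberg adjusted p below 0.05 in each comparison was called. Log2 fold changes are from that fit and levels are TMM-scaled CPM. A region counted as bound when it overlapped a FLAG site, with windows of 200 bp around point sites (FLAG, Grg, p300, Med1 and Sox2). Bound regions, 26 gene lists and genes near FLAG sites were tested with limma camera on log2 CPM (prior 2) with a preset correlation of 0.01 and, beside it, an estimated one, each adjusted over its family. Near genes were those nearest to a FLAG site and within 50 kb of it. A gene within 50 kb of sites that each had a closer gene counted among the others. Med1, Sox2 and H3K27me3 libraries were compared as medians against 10000 random draws matched in 20 bins of level, and day 6 overlap likewise with pMN level. The reference used gives no strand, so the distance to a gene is that to its span and not to its start, which departs from the plan. A gene span was found for 29777 of 39017 genes, and 1386 of the genes tested had none. Of the gene rows, 35763 matched the list of gene names.

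Named genes followed a rule written before the data were examined, as were the groups, the main tests, the lists and most alternatives. The rule took, per comparison, the 8 genes with the largest fold in each direction among those called, at 4 CPM or more in the higher group and with no overlap of libraries, then 24 genes chosen in advance, and the members with the smallest p of each list described. It also took the 3 regions with the largest fold per direction and antibody (called, above the median CPM, no overlap), and the strongest FLAG site in iNkx2.2 within 50 kb of each chosen gene with the regions over it. Text names those of these genes that kept their call in every alternative, and gives the alternative where it did not. Where a group held 3 reads or fewer, the ratio of summed reads is given with a 95% counting interval. Nkx2-2, Olig2, Pax6, Nkx2-9, Gli1, Gli2, Sox2, Dbx2, Tle2, Tle4, Tle6, Upk3a, Unc80, Cdh22, Adamtsl2, Phox2a, Hey1, Dll4, Spon1, Ccnd2, Ddc, Lmx1b, Aldh18a1, Map2, Rtl1, Epha10, Atp2b4, Gm16551, Syt6, Stk32a, Ntn1, Mbp, Esrrb and Erbb3 overlap another gene span, and their counts are uncertain to that extent. No span was found for Aes, 1700106J16Rik, Fam69c, D030046N08Rik and mt-Nd2.

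RNA replicates carry the same numbers in each state, and a check of the deviations from group means found same-numbered libraries correlated at 0.153 to 0.629 and others at -0.412 to 0.055. The numbers therefore pair the RNA libraries, by the data and not by a statement in the labels. The main RNA tests and the estimated correlations used no block, so effects shared by same-numbered libraries stay in their spread and correlation. An estimated correlation with the block was not computed. Summed over the genes or regions of their own tables, which is not the sequencing depth, RNA libraries held 16.8 to 46.8 M counts, FLAG 2.32 to 9.40, Grg 1.45 to 6.25, HDAC2 0.632 to 1.49, p300 0.999 to 3.37, H3K27ac 3.31 to 7.06, H3K4me1 4.95 to 8.52, Med1 1.03 to 3.20, Sox2 1.16 to 4.12 and H3K27me3 2.03 to 2.50. Scripts were tested on simulated data with 200 changed genes (seed 155). At the counts and replicate spread of these libraries a 2-fold change was recovered for 64.6% of changed genes and a 4-fold change for 91.9% in RNA, with 14 of 14973 unchanged genes called. For regions the shares were 16.0% and 95.0% for FLAG, 2.00% and 27.0% for Grg and 49.0% and 99.0% for H3K27ac. With only 200 changed, the adjusted cutoff is stricter than where many regions change, so these shares are not the power of the real comparisons. Pairs of replicates differed by more than counting error, and no duplicates were found.

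Alternatives planned before the data were examined were the 5000 strongest FLAG sites, a replicate block, day 6 peaks of a single replicate, 10 or 100 kb, an estimated correlation, leaving out each library, no filter, regions above the median CPM, RLE or no TMM scaling, a 50% overlap, a FLAG centre inside the region, DESeq2 Wald tests, only the 2 groups compared, Med1 by edgeR and limma on log2 FPKM with a pseudocount of 1 (genes at 1 FPKM or more in 3 libraries, 12543 tested). Added after the data were seen were the authors' log2 CPM, library totals from peak list headers, 500 bp windows, FLAG sites with no call and FLAG sites that differ by under 0.25 log2. Comparisons that share the pMN libraries were set against 20 simulations for RNA and 10 for ChIP, which drew libraries without pairing.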

Results

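Mouse embryonic stem cells were turned into spinal motor neuron progenitors (pMN) with retinoic acid and a Smoothened agonist, an activator of Hedgehog signalling, and collected on day 4. The progenitors carried no induced factor (pMN), FLAG-tagged Nkx2.2 induced with 1 µg/mL doxycycline for 14 to 16 h (iNkx2.2), or a FLAG-tagged Nkx2.2 with a mutated TN domain induced in the same way (iTNmut). Nkx2.2 is the homeodomain factor of the p3 progenitors that lie next to the pMN domain, and the TN domain is the part of such factors that contacts Groucho/TLE (Grg) corepressors. RNA was sequenced with n = 3 libraries per state. Chromatin immunoprecipitation was sequenced for the FLAG tag (n = 2 in each induced state), for Grg, HDAC2, p300, H3K27ac and H3K4me1 (n = 2 per state), and for Med1, Sox2 and H3K27me3 (1 library per state, with 2 for Med1 in iTNmut). H3K27ac was also measured in day 6 motor neurons (n = 2). Levels below are means of library-scaled counts (CPM) ± SD between libraries, and log2 fold changes are given ± SE.

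The level of the induced gene was measured first. Nkx2-2 RNA was 9.13 ± 3.37 CPM in pMN, 351 ± 19.4 in iNkx2.2 and 225 ± 34.8 in iTNmut (n = 3 each). It rose 38.1-fold with the intact factor (log2 fold change 5.25 ± 0.25, adjusted p = 1.74e-06) and 24.5-fold with the mutant (4.61, adjusted p = 2.1e-05). Between the induced states the difference was 0.64 ± 0.20 log2 (adjusted p = 0.0717), and with the replicate number as a block it passed (adjusted p = 0.0197), as it did without pMN 2 (adjusted p = 0.00717), by DESeq2 (adjusted p = 0.0233), with no expression filter (adjusted p = 0.0122) and with only those 2 groups in the fit (adjusted p = 0.00969). The counts cannot part the transgene from the endogenous gene, whose span also overlaps Nkx2-2os.

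Which genes changed in iNkx2.2 against pMN? Both came from the same line, but only iNkx2.2 had doxycycline, so doxycycline cannot be parted from the intact factor in this comparison. Several genes of pMN progenitors fell. Olig2, the basic helix-loop-helix factor that specifies motor neuron progenitors, went from 250.3 ± 47.8 CPM in pMN to 5.85 ± 4.02 in iNkx2.2 (n = 3 each), a 40.8-fold fall (log2 -5.35 ± 0.40, adjusted p = 3.77e-05). Pax6, a homeodomain factor that Nkx2.2 opposes in the ventral spinal cord, fell 46.2-fold to 2.49 ± 0.291 CPM, and the proneural factor Neurog2 fell 79.0-fold to 1.24 ± 0.52. Olig1, the forkhead gene Foxb1, the LIM homeobox gene Lhx4, the homeobox gene Nkx2-9 and the metalloproteinase gene Pappa fell 34.0-, 38.6-, 34.9-, 29.8- and 31.3-fold. Of these, Nkx2-9 belongs to the p3 and V3 list used here and not to the pMN progenitor list. Upk3a (a uroplakin) rose 28.3-fold, Unc80 (a subunit of the NALCN sodium leak channel) 14.6-fold, Cdh22 (a cadherin) 11.6-fold, Adamtsl2 11.2-fold, Phactr3 8.71-fold and the Groucho-related gene Tle6 8.52-fold. Uncx, a homeobox gene of V3 interneurons, rose as well: its 3 libraries held 437 reads in iNkx2.2 and 3 in pMN, a ratio of 86.7 (95% counting interval 29.5 to 422).

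The pMN progenitor list moved down with the intact factor: of 14 genes tested, 7 fell, none rose and the others did not pass (median log2 -0.95, camera adjusted p = 2.93e-08; adjusted over the list alone, 1 rose and 8 fell). Of 11 Hedgehog pathway genes, 7 fell and 0 rose (median -1.47, adjusted p = 6.2e-08; over the list alone 1 and 7). Among them were Gli1, the transcriptional target and effector of the pathway, which fell 7.99-fold to 21.9 ± 4.65 CPM, Gli2 (14.3-fold) and the receptor gene Ptch1 (2.22-fold). Of 18 cell cycle genes 6 fell and 0 rose (median -0.28, adjusted p = 3.51e-06; over the list alone 0 and 7), including the replication genes Mcm6 (1.51-fold) and Rrm2 (1.48-fold). Of 12 ATF4 target genes 6 fell and 0 rose (median -0.59, adjusted p = 0.00023; over the list alone 0 and 8), including the serine synthesis gene Psat1 (2.25-fold) and Aldh18a1 (1.51-fold). Floor plate genes went up, with 5 of 10 higher and 0 lower both overall and over the list alone (median 0.48, adjusted p = 0.00601): Foxa2, the forkhead factor of the floor plate, rose 1.65-fold to 97.7 ± 6.96 CPM and Spon1 2.55-fold. None of these calls held with an estimated correlation, at adjusted p = 0.0521 for pMN progenitor, 0.0653 for Hedgehog, 0.231 for cell cycle, 0.73 for ATF4 and 0.282 for floor plate genes.

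The motor neuron and Notch lists passed less firmly. Of 19 motor neuron genes 1 rose and 6 fell (median -0.45, adjusted p = 0.00601; the same counts over the list alone), with the LIM factor Lhx3 down 28.7-fold and the homeobox gene Mnx1 down 4.71-fold. The call was lost without pMN 3 (adjusted p = 0.119) or iNkx2.2 2 (adjusted p = 0.0503). Of 17 Notch pathway genes 5 rose and 2 fell (median 0.27, adjusted p = 0.00881; over the list alone 7 and 2): the transcriptional repressor Hey1 rose 3.54-fold to 166 ± 23.2 CPM, the glycosyltransferase gene Mfng 1.94-fold and the ligand gene Jag1 1.76-fold, and the ligand gene Dll4 fell 2.65-fold. That call was lost without pMN 2 (adjusted p = 0.0573). The adjusted p with an estimated correlation was 0.918 for the motor neuron list and 0.803 for the Notch list.

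Other lists did not pass as groups, although single members changed. Of 6 p3 and V3 interneuron genes 4 rose and 2 fell (median 1.70, adjusted p = 0.428). Those that fell were Nkx2-9 (log2 -4.90) and Nkx2-1 (-3.68). Of p2 and V2 genes 2 rose and 3 fell (adjusted p = 0.542; over the list alone 3 and 4), and of p1 and p0 genes 2 rose and 1 fell (adjusted p = 0.945), with a median of -0.05 and a mean of 0.04. Among 20 genes of transcriptional cofactors 3 rose and 1 fell (adjusted p = 0.945, median -0.03, mean 0.28; over the list alone 3 and 2): Tle2 rose 8.14-fold and Aes 2.35-fold, while Tle1 fell 2.02-fold to 39.1 ± 5.41 CPM. Pan-neuronal genes (3 rose, 0 fell; adjusted p = 0.23, passing without pMN 1 at adjusted p = 0.0437) included the synaptic vesicle gene Syp, up 2.14-fold. Pancreatic endocrine genes (1 rose, 2 fell; adjusted p = 0.698, median 0.63, mean -0.03; over the list alone 2 and 2) included Insm1, a zinc finger factor of endocrine and neuronal precursors, up 5.87-fold, and the hormone gene Sst, down 14.0-fold. Serotonergic genes (1 rose, 1 fell; adjusted p = 0.945), retinoic acid genes (0 rose, 3 fell; adjusted p = 0.945, median 0.39; over the list alone 1 and 3) and Hox genes (1 rose, 1 fell of 18; adjusted p = 0.698) were mixed. Neural crest genes (1 rose; adjusted p = 0.23, passing without iNkx2.2 1 at adjusted p = 0.046; over the list alone 2 rose) and p53 target genes (1 rose; adjusted p = 0.98, median -0.04, mean 0.01) did not pass either. No gene was called among immediate early (adjusted p = 0.191; 0.0206 with the replicate block, 0.0293 without pMN 3), pluripotent (0.68), dorsal (0.698), endoderm (0.726), endothelial and blood (0.945, median 0.08, mean -0.02), mitochondrial (0.945), oligodendrocyte (0.945) and mesoderm (0.956) genes. With the replicate block single members of these lists passed, among them Egr1 (0.00188), Dusp1 (0.0116) and Btg2 (0.0291) of the immediate early, Esrrb (0.0145) of the pluripotent, Pax3 (0.0391) of the dorsal, Sox17 (0.0281) of the endoderm, mt-Nd2 (0.0345) of the mitochondrial, Mbp (0.00238) and Cspg4 (0.0147) of the oligodendrocyte and Foxc2 (0.00726) of the mesoderm genes. Without some single library 2 of the 3 called pan-neuronal genes, all 3 retinoic acid genes and 1 called gene or more of the floor plate, ATF4, Notch, p3 and V3, p2 and V2, p1 and p0, pancreatic and Hox lists lost their call.

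Of 15388 genes tested with edgeR, 986 were higher and 923 lower in iNkx2.2 than in pMN, 1909 in all, and 1904 of these showed no overlap between the libraries of the groups. Across all genes tested 31.5% showed none, where chance gives 10% with 3 against 3. With the replicate number as a block the count was 5061, and it was 942 without pMN 1, 1067 without pMN 2, 917 without iNkx2.2 1 and 1191 without iNkx2.2 3. With limma on log2 FPKM the higher share of the calls was 67.8%, against 51.6% here. The authors' deposited table calls 735 genes higher and 675 lower among 10158, of which 611 and 672 were shared with these calls and 0 were opposite.

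What did the TN mutant change against pMN? Olig2, Gli1 and Pax6, which fell with the intact factor, did not pass here: Olig2 was 213 ± 31.3 CPM (log2 -0.23, adjusted p = 0.85), Gli1 171 ± 25.2 (-0.04, adjusted p = 0.96), Pax6 80.7 ± 2.77 (-0.52, adjusted p = 0.167), and Olig1 (-0.66, adjusted p = 0.338), Irx3 (0.60, adjusted p = 0.271) and Ptch1 (-0.12, adjusted p = 0.757) did not either. Neurog2 fell 3.64-fold to 29.0 ± 10.8 CPM (adjusted p = 0.00336). The receptor gene Prokr2 rose 16.3-fold to 20.1 ± 2.06 CPM, the muscle methyltransferase gene Smyd1 15.9-fold, Upk3a 13.7-fold, the retrotransposon-derived gene Rtl1 6.42-fold, the ephrin receptor gene Epha10 6.01-fold and the calcium pump gene Atp2b4 5.58-fold. The homeobox gene Meox1 fell 9.56-fold, Vtn (vitronectin) 8.64-fold, Shisa3 6.46-fold, Phox2a, a homeobox gene of visceral motor neurons, 6.09-fold, Gm16551 6.08-fold, Mnx1 5.58-fold and the synaptotagmin gene Syt6 5.41-fold.

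Several lists moved down in iTNmut and kept their call without any single library. Of motor neuron genes 7 fell and 0 rose (median -1.42, adjusted p = 3.05e-05; over the list alone 3 rose and 13 fell), with Mnx1 and Tbx20, a T-box gene of cranial motor neurons, down 5.58- and 5.33-fold. Of pMN progenitor genes 3 fell and 0 rose (median -0.59, adjusted p = 3.05e-05, over the list alone 1 and 8). The called members were Neurog2, Dbx2 (log2 -2.58) and Sox2 (-0.42), while Olig2, Olig1 and Pax6 of that list did not pass. Floor plate genes, which rose with the intact factor, went the other way, with 3 lower and 0 higher (median -0.70, adjusted p = 0.000221; over the list alone 1 and 6), including Ntn1, the netrin guidance cue, down 1.85-fold to 170 ± 5.8 CPM. The p3 and V3 list had 2 lower (median -1.57, adjusted p = 0.000251; over the list alone 4), the cell cycle list 1 lower (median -0.20, adjusted p = 0.000221; over the list alone 3) and the serotonergic list 2 lower (median -1.22, adjusted p = 0.0104; over the list alone 2), where Ddc, the aromatic amino acid decarboxylase, fell 4.37-fold. Of 7 mesoderm genes 3 fell (median -1.24, adjusted p = 0.000668; over the list alone 4), among them Meox1 and the mesenchymal factor Twist1 (5.68-fold). Pancreatic endocrine genes moved down with 0 called (median -0.77, adjusted p = 0.00608; over the list alone 2 of 6 lower), although Insm1 (0.00227), Neurod1 (0.00227) and Sst (0.00634) passed with the replicate block. With an estimated correlation the adjusted p was 0.403, 0.145, 0.145, 0.145, 0.234, 0.165, 0.229 and 0.365 for these lists in the order given. Member counts were less stable than the list tests: without some single library 2 of the 3 called pMN progenitor genes, 1 of the 2 p3 and V3 genes, the called cell cycle gene, 1 of the 3 mesoderm genes and 1 motor neuron gene or more lost their call.

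Further lists in iTNmut depended on single libraries. Pan-neuronal genes had 1 lower of 12 (median -0.63, adjusted p = 0.0034; 0.573 with an estimated correlation, 0.0554 without pMN 1, 0.0607 without pMN 3, 0.0687 without iTNmut 2), the RNA-binding protein gene Elavl4 (log2 -1.32). Endoderm genes had 1 lower of 8 (median -1.83, adjusted p = 0.0144; 0.566 with an estimated correlation, 0.0554 without pMN 1, 0.103 without pMN 3, 0.074 without iTNmut 1), Hedgehog genes 1 lower (median -0.12, adjusted p = 0.0246; 0.365 with an estimated correlation, 0.0724 without pMN 3, 0.074 without iTNmut 1). The called endoderm gene and the called Hedgehog gene each lost their call without some single library. Notch pathway genes had 2 higher and 4 lower (median -0.20, adjusted p = 0.0269; 0.566 with an estimated correlation, 0.139 without pMN 1, 0.0724 without pMN 3, 0.0807 without iTNmut 3), with Jag1 up 2.21-fold and Dll4, Dll3 and Hes6 down 3.48-, 2.31- and 1.75-fold. The other 14 lists did not pass, at adjusted p from 0.0627 to 0.935. Of these, ATF4 (0.0132), p53 (0.0299), pluripotent (0.0156) and immediate early genes (0.0278) passed with the replicate block. Without a single library, ATF4 genes passed without pMN 3 (0.00458) or iTNmut 2 (0.000705), p53 genes without pMN 3 (0.0354), iNkx2.2 1 (0.0372), iNkx2.2 3 (0.0364) or iTNmut 1 (0.0224), and pluripotent genes without pMN 1 (0.0326), iNkx2.2 1 (0.0487) or iTNmut 2 (0.0296). Immediate early genes passed without pMN 2 (0.0256) or iTNmut 3 (0.0181), dorsal genes without pMN 1 (0.0255), mitochondrial genes without pMN 2 (0.0151) and oligodendrocyte genes without iTNmut 2 (0.0296).

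In iTNmut against pMN, 241 genes were higher and 217 lower, 458 in all by edgeR, each with no overlap between the libraries of the groups (17.5% of all genes tested, chance 10%). With the replicate block the count was 1885, and it was 246 without pMN 1, 294 without pMN 3, 290 without iTNmut 1 and 289 without iTNmut 2. The authors' deposited table has 132 higher and 102 lower, of which 132 and 98 were shared and 0 opposite. The pMN libraries came from the uninduced iNkx2.2 line, so line and doxycycline cannot be parted from the mutant factor in this comparison. The intact factor and the mutant shared 109 higher and 77 lower genes, with 33 called in opposite directions. Unchanged groups that shared simulated pMN libraries, without the pairing of replicate numbers, gave 0, 0.05 and 0. Only 0.25 and 0.35 genes were called per comparison in that simulation, so these counts had to lie near 0. They cannot show how many of the shared calls come from the shared controls. Independent lists of the observed sizes would share 15.4, 13.0 and 28.4. The fold changes correlated at 0.345 (0.519 in the simulation), and their covariance was 0.107 against a simulated 0.0434, a difference of 0.0634. The 3 pMN libraries are too few to split, so part of the excess may come from these shared controls.

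Which changes separated the intact factor from the mutant when compared directly? Some pMN genes were lower with the intact TN domain. Olig2 was 34.7-fold lower in iNkx2.2 than in iTNmut (log2 -5.12, adjusted p = 4.08e-05), Pax6 32.1-fold, Neurog2 21.7-fold, Olig1 21.5-fold and Foxb1 18.6-fold. Stk32a, a kinase gene, was 25.2-fold lower, Fam69c 98.9-fold and D030046N08Rik 50.6-fold. Higher with the intact factor were Phox2a (41.4-fold, 53.2 ± 15.9 against 1.26 ± 0.17 CPM), 1700106J16Rik (25.6-fold), Fam163a (23.7-fold), Hepacam2 (23.4-fold), Shisa3 (17.4-fold), Phactr3 (11.4-fold) and Vtn (11.3-fold). Uncx had 437 reads in the iNkx2.2 libraries and 2 in the iTNmut libraries, a ratio of 169 (95% counting interval 46.6 to 1400). Sim1, the transcription factor of V3 interneurons, had 114 and 3, a ratio of 29.4 (9.82 to 145).

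By list, floor plate genes were higher with the intact factor, 6 higher and 0 lower (median 1.29, adjusted p = 4.17e-06; over the list alone 8 and 0), with Foxa2 at 2.37-fold and Ntn1 at 2.52-fold. Hedgehog genes were lower, 1 higher and 6 lower (median -1.03, adjusted p = 6.05e-06; over the list alone 1 and 7), with Gli1 at 7.75-fold, Gli2 at 12.1-fold and Ptch1 at 2.04-fold. Of pMN progenitor genes 2 were higher and 7 lower (median -0.50, adjusted p = 0.000987; over the list alone 3 and 7), and the other 5 did not pass. Notch pathway genes (7 higher, 2 lower; median 0.39, adjusted p = 0.000987; over the list alone 8 and 3) included Hey1 at 5.19-fold and Dll3 at 3.26-fold higher. Pan-neuronal genes (5 higher, 0 lower; median 0.77, adjusted p = 0.000987; over the list alone 6 and 0) included the neuronal tubulin gene Tubb3 at 3.73-fold, Elavl4 at 3.63-fold and Map2 at 3.62-fold. Mesoderm genes (2 higher; median 1.22, adjusted p = 0.00229; over the list alone 3) included Meox1 at 10.1-fold, and serotonergic genes (2 higher; median 0.86, adjusted p = 0.0103; over the list alone 3) included the LIM factor gene Lmx1b at 5.30-fold. With an estimated correlation the adjusted p was 0.129, 0.129, 0.157, 0.384, 0.476, 0.307 and 0.157 for these lists in the order given. Without some single library 1 of the 2 called mesoderm genes, 1 of the 2 serotonergic genes and 1 gene or more of the pMN progenitor and Notch lists lost their call.

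The other lists that passed in that comparison each lost their call without some library. ATF4 genes (2 lower; median -0.52, adjusted p = 0.0103) were lost without iTNmut 2 (adjusted p = 0.0973), and immediate early genes (2 higher; median 0.51, adjusted p = 0.0103) without iTNmut 1 (0.0542). Cell cycle genes (1 higher, 2 lower, such as the cyclin gene Ccnd2 at 2.19-fold lower; median -0.14, adjusted p = 0.0153) were lost without iNkx2.2 1 (0.052) or iTNmut 2 (0.0592), and pluripotent genes (1 higher; median 1.27, adjusted p = 0.0248) without iNkx2.2 2 (0.0889) or iTNmut 1 (0.0578). The p3 and V3 list (3 higher, 1 lower; median 2.22, adjusted p = 0.0268; over the list alone 4 and 2) was lost without iNkx2.2 1 (0.104) or iNkx2.2 3 (0.0562) and with the replicate block (0.0729), where Nkx2-9 was 8.83-fold lower. Neural crest genes (0 called; median 0.91, adjusted p = 0.0401) were lost without iNkx2.2 2 (0.119), iNkx2.2 3 (0.0566) or iTNmut 1 (0.0656), and Erbb3 (0.0033), Ets1 (0.00649) and Snai2 (0.0172) passed with the replicate block. Pancreatic genes (3 higher; median 1.09, adjusted p = 0.0401; over the list alone 4 and 1) were lost without pMN 1 (0.0521), pMN 3 (0.0566), iNkx2.2 1 (0.154) or iTNmut 2 (0.0973) and with the block (0.064). Adjusted p with an estimated correlation was 0.476 for ATF4, immediate early, pluripotent and pancreatic genes, 0.473 for cell cycle, 0.373 for p3 and V3 and 0.384 for neural crest genes. Without some single library both called immediate early genes, 1 of the 2 ATF4 genes, 2 of the 3 cell cycle genes, the called pluripotent gene and 2 of the 3 pancreatic genes lost their call. The other 12 lists did not pass, at adjusted p from 0.0838 to 0.919, of which dorsal genes passed with the block (0.0391) and without pMN 1 (0.0364), pMN 2 (0.0485), iNkx2.2 1 (0.00725) or iTNmut 3 (0.0356), endoderm genes without iNkx2.2 2 (0.00659) and p53 genes without iNkx2.2 3 (0.0123).

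Directly compared by edgeR, 912 genes were higher and 756 lower in iNkx2.2 than in iTNmut, 1668 in all, and 1667 of them had no overlap between the libraries (31.3% of all genes tested, chance 10%). The replicate block gave 5070, and the count was 878 without iNkx2.2 1 and 1027 without iTNmut 1. The higher share of calls was 54.7% here, 67.2% with limma on log2 FPKM and 65.8% with no expression filter. The authors' deposited table has 655 higher and 556 lower, of which 506 and 548 were shared and 0 opposite. iTNmut is a separate cell line, so line and mutation cannot be parted.

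**Figure D1:**
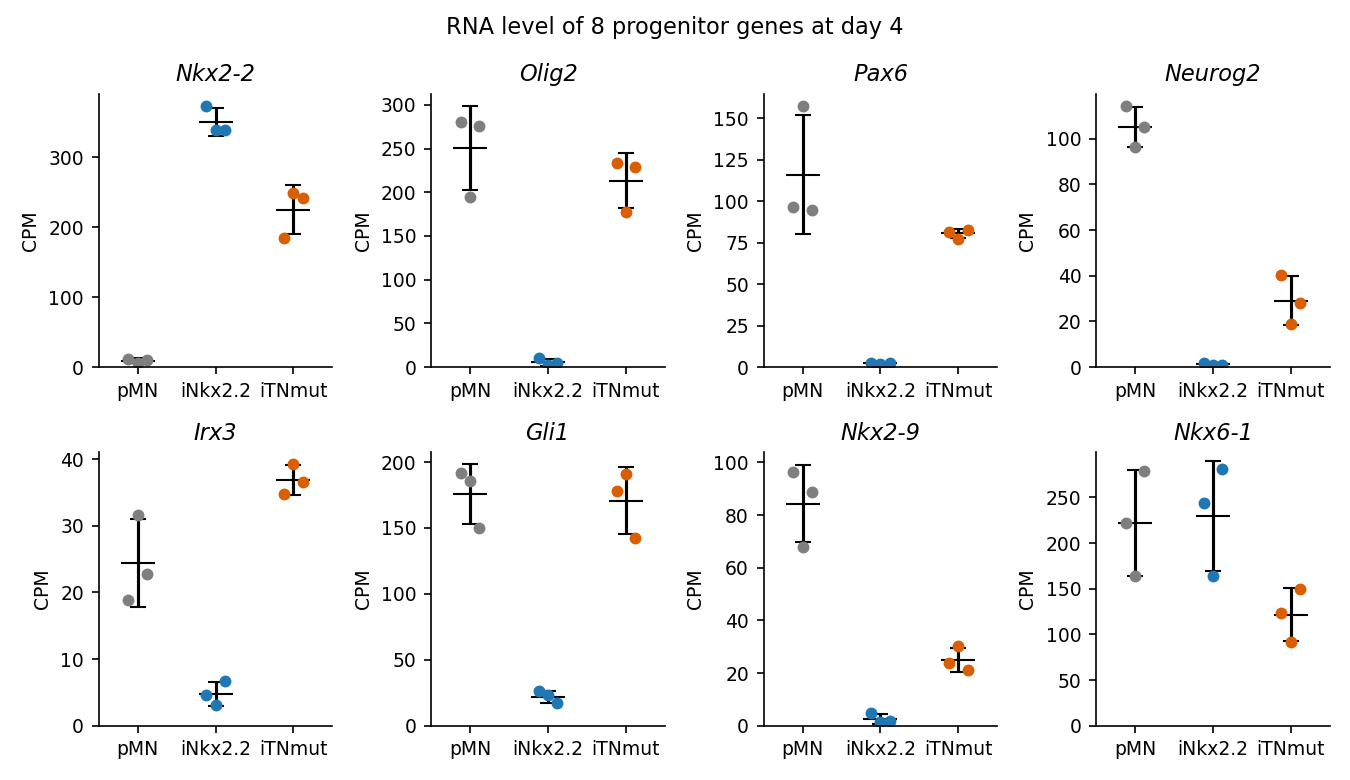
RNA level in CPM of 8 genes in pMN, iNkx2.2 and iTNmut libraries, with points for libraries and bars for mean ± SD (n = 3). Olig2 was 250.3 in pMN, 5.85 in iNkx2.2 and 213 in iTNmut, whereas Nkx2-2 was 9.13, 351 and 225.

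Where did the tagged proteins bind? At 22001 FLAG sites, edgeR called 5023 higher and 4793 lower in iNkx2.2 than in iTNmut (n = 2 each). The largest differences toward the intact factor were at a site 41408 bp from Nhlrc3 (156 ± 73.3 against 7.74 ± 0.726 CPM, log2 4.33, adjusted p = 4.51e-23), inside Basp1 (4.25) and inside Nlgn1, a synaptic adhesion gene (4.17). Those toward the mutant were inside Dab1, an adaptor of reelin signalling (4.22 ± 0.00476 against 59.6 ± 4.17 CPM, log2 -3.81), inside Heatr1 (-3.69) and 6805 bp from Nfatc4 (-3.53). Of the sites, 17541 lay within 50 kb of a gene span. The higher share of calls was 51.2% with TMM scaling and 40.3% with column totals, and 6067 to 10165 sites were called when each library was left out.

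Did Grg, the partner of the TN domain, follow the proteins? Grg regions that overlapped a FLAG site gained Grg signal with both proteins, whereas the median of the other regions fell. Against pMN, the median log2 fold change at 13098 bound regions minus that at 8828 other regions was 2.59 in iNkx2.2 (camera adjusted p = 3.09e-32) and 1.70 in iTNmut (adjusted p = 4.47e-35). Both held with an estimated correlation (adjusted p = 0.00716). The bound regions' own medians were 1.21 and 0.74, and those of the other regions -1.37 and -0.96. Own medians depend on scaling, and RLE moved the median of all Grg regions by -0.231 and -0.168. In iNkx2.2, 51.1% of bound regions were higher and 12.0% lower than in pMN, against 13.9% and 54.6% of the others. Between the proteins the difference was 0.68 (camera adjusted p = 8.84e-05), and with an estimated correlation it was lost (adjusted p = 0.0661). Of bound regions 18.9% were higher and 10.9% lower, against 12.9% and 21.1% of the others. The bound regions' own median was 0.24 in that comparison, and that of the others -0.44. By class of site the bound median was 1.43 with more intact factor, 0.07 with no FLAG call and -1.33 with more mutant. A site inside Cdk5rap1 went from 0.339 ± 0.48 CPM in pMN to 79.2 ± 6.04 in iNkx2.2 and a site inside Chsy1 from 0.689 ± 0.0137 to 156 ± 61.8, while sites inside Khdrbs2 (from 114 to 1.69 CPM), 83766 bp from Il12b and 7609 bp from Cpsf4l fell (log2 -6.00, -5.92 and -5.91). In all, 7919 Grg regions were higher and 6398 lower in iNkx2.2 than in pMN, 5475 and 4012 in iTNmut, and 3610 and 3284 between the proteins, and when each library was left out the last 2 totals spanned 5599 to 9423 and 2383 to 8576. The 2 comparisons with pMN shared 4662 higher and 3003 lower regions and 65 opposite ones (independent lists: 1980, 1170 and 3050), and the covariance of their fold changes was 2.95 (0.139 in unchanged simulated groups, difference 2.81). The pMN libraries came from another line without doxycycline. Such an offset enters both comparisons but not the simulation, so how much of the sharing comes from these controls cannot be told.

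HDAC2, a histone deacetylase, rose at bound regions with both proteins. The HDAC2 pMN libraries, too, came from another line without doxycycline, and neither can be parted from the proteins here. The bound minus other difference was 0.37 in iNkx2.2 (6888 bound, 8778 other; adjusted p = 9.55e-14) and 0.38 in iTNmut (adjusted p = 1.44e-25), and between the proteins it was -0.02 (adjusted p = 0.816). That direct value passed at 0.21 by unadjusted camera p with the 5000 strongest FLAG sites and ranged from -0.16 to 0.14 when each library was left out. In iNkx2.2 18.6% of bound and 1.66% of other regions were higher than in pMN, and in iTNmut 9.07% and 0.0342%. Neither call held with an estimated correlation (adjusted p = 0.135 and 0.102). Regions inside Edil3 (15.6 ± 7.71 to 170 ± 4.41 CPM, log2 3.50), 5828 bp from Hes2 (3.17) and inside Gtdc1 (3.03) rose most in iNkx2.2, and a region 255971 bp from Tox (-2.40) and a region 22514 bp from Gm22296 (-2.38) were among those that fell most. The 2027 calls against pMN in iNkx2.2 (1427 higher, 600 lower), 690 in iTNmut (628, 62) and 1809 between the proteins (1047, 762) spanned 291 to 2382, 48 to 1326 and 223 to 2410 when each library was left out.

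How did enhancer marks behave where Nkx2.2 bound? The acetyltransferase p300 was higher at bound regions in both induced states, and most with the mutant. Its bound minus other difference was 0.48 in iNkx2.2 (11191 bound, 18914 other; adjusted p = 1.01e-08) and 1.12 in iTNmut (adjusted p = 6.47e-38) against pMN, and -0.66 between the proteins (adjusted p = 8.26e-07). In iTNmut 30.1% of bound and 2.90% of other p300 regions were higher than in pMN, and 25.03% of bound and 8.89% of other regions were lower in iNkx2.2 than in iTNmut. H3K4me1, a mark of enhancers, followed with 0.17 (adjusted p = 0.000116), 0.28 (adjusted p = 1.13e-14) and -0.12 (adjusted p = 0.000245; 9906 bound, 35310 other). H3K27ac, the acetylation of active enhancers, showed 0.00 with the intact factor (4438 bound, 13920 other, adjusted p = 0.859), 0.17 with the mutant (adjusted p = 1.69e-06) and -0.18 between the proteins (adjusted p = 2.86e-07). In iNkx2.2 16.9% of bound regions were higher and 14.3% lower than in pMN, against 11.5% and 7.39% of others. With the 5000 strongest FLAG sites that H3K27ac difference was -0.15, which passed by unadjusted camera p. Between the proteins 16.81% of bound and 1.80% of other H3K27ac regions were lower with the intact factor. With an estimated correlation none held: in the order iNkx2.2, iTNmut and direct, adjusted p = 0.146, 0.0616 and 0.182 for p300, 0.135, 0.0616 and 0.135 for H3K4me1, and for H3K27ac 0.144 in iTNmut and 0.135 directly.

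Grouped by FLAG signal, bound regions split by which protein bound more. At sites with more of the intact factor, at sites with no FLAG call and at sites with more of the mutant, the direct Grg difference was 1.87, 0.51 and -0.89, that of p300 0.69, -0.63 and -1.45, that of H3K27ac 0.84, -0.12 and -0.31, that of HDAC2 1.00, -0.02 and -0.54, and that of H3K4me1 0.41, -0.10 and -0.38. For H3K27ac in iNkx2.2 against pMN the same classes gave 0.72, 0.04 and -0.11. None of these classes was compared with another by a test.

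H3K27ac regions inside Gli2 and Pappa, whose RNA fell with the intact factor, fell most in iNkx2.2 against pMN: inside Gli2 from 100.4 ± 10.8 to 8.82 ± 1.46 CPM (log2 -3.51, adjusted p = 3.64e-05) and from 94.7 ± 0.478 to 8.86 ± 1.64 (-3.41), and inside Pappa from 96.8 ± 18.1 to 9.20 ± 0.377 (-3.39). Regions inside Clpb (19.2 ± 1.93 to 130 ± 26.2, log2 2.74), 86826 bp from the T-box gene Tbx20 (2.72) and 51771 bp from Rgs2 (2.69) rose most. For p300 the leading regions were 197256 bp from Gm26018 (3.94), inside Kcnip4 (3.83) and inside the glutamate receptor gene Grm8 (3.75), with a fall inside Gm6999 (-4.32), and for H3K4me1 inside Zfp831 (3.30), Mphosph9 (2.74) and Clpb (2.42), with falls 84178 bp from Il12b (-2.18), inside Ptprc (-2.17) and inside Dcdc5 (-2.06). By edgeR, H3K27ac regions higher and lower numbered 2358 and 1664 in iNkx2.2 against pMN, 1122 and 936 in iTNmut, and 1561 and 996 directly. Scaled to the library totals of the peak lists, H3K27ac calls against pMN were 892 higher and 5961 lower in iNkx2.2, and the higher share fell from 58.6% to 13.0%, in iTNmut from 54.5% to 34.0% and directly from 61.0% to 28.2%. The bound minus other differences do not depend on such a factor. For p300 there were 3463 and 3052, 3913 and 1667, and 3416 and 4483 (70.1% higher in iTNmut, 60.0% with column totals, 59.0% from the authors' log2 CPM), and for H3K4me1 5764 and 5815, 3977 and 2858, and 2595 and 2925 (49.8%, 58.2% and 47.0% higher; 34.0%, 31.4% and 58.6% with the library totals of the peak lists). In the order iNkx2.2, iTNmut and direct, the totals when each library was left out spanned 638 to 6630, 635 to 6917 and 1555 to 8296 for p300, 1907 to 4237, 648 to 2585 and 941 to 3367 for H3K27ac, and 5229 to 13885, 2269 to 10038 and 1118 to 8692 for H3K4me1. The 2 H3K27ac comparisons with pMN shared 554 higher, 565 lower and 39 opposite regions (independent lists: 144, 84.8 and 222), with a covariance of 0.234 (simulated 0.0357, difference 0.198). This simulation, too, held no offset from the pMN lines or the absence of doxycycline, so it cannot tell how much comes from the shared controls.

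**Figure D2:**
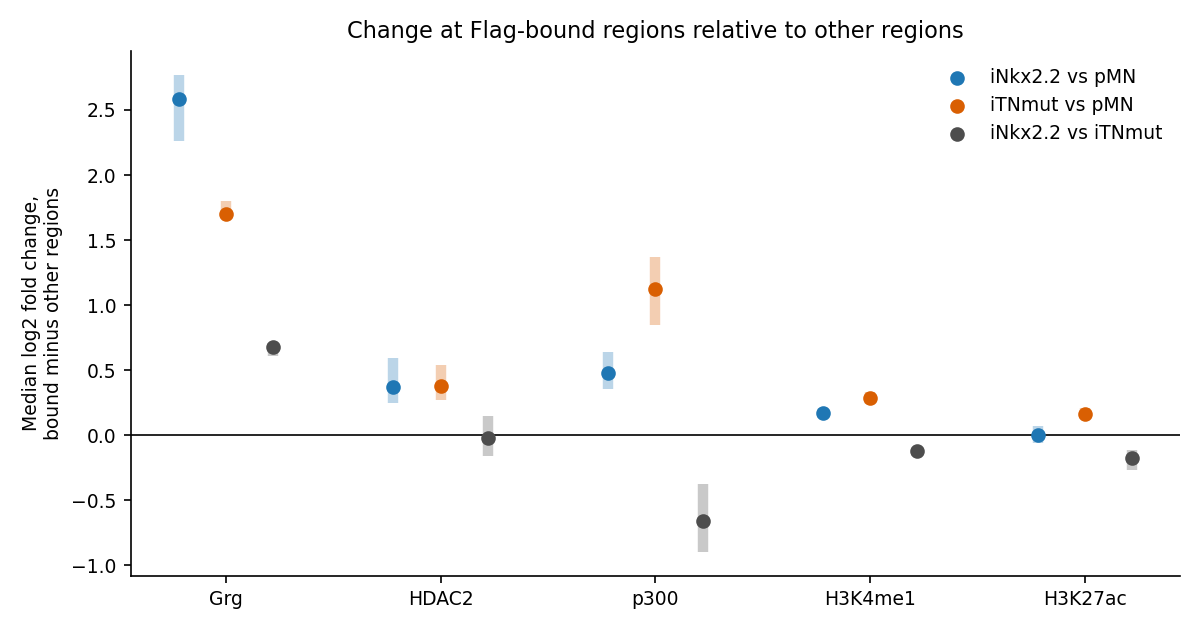
Median log2 fold change at Nkx2.2-bound regions minus that at other regions for 5 antibodies in 3 comparisons (n = 2 libraries per state), with pale bars for the range when each library is left out. Grg stood at 2.59 in iNkx2.2 and 1.70 in iTNmut against pMN, while H3K27ac stood at 0.00 and 0.17.

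The strongest FLAG site near Olig2 lay at position 91193355 of chromosome 16. Both proteins were there (394 ± 159 CPM in iNkx2.2 and 332 ± 24.4 in iTNmut, n = 2 each, adjusted p = 0.716), and Grg was 323 ± 189, 438 ± 133 and 384 ± 63 CPM in pMN, iNkx2.2 and iTNmut with no call. H3K27ac over the site fell with the intact factor from 140 ± 40.6 to 14.3 ± 5.39 CPM (log2 -3.28, adjusted p = 4.85e-05), whereas in iTNmut it was 106 ± 6.54 (-0.40, adjusted p = 0.352), and the direct difference was -2.89 (adjusted p = 0.000196). At the site 3829 bp from Neurog2, FLAG was lower for the intact factor (41.0 ± 16.1 against 125 ± 40.7 CPM, log2 -1.58, adjusted p = 3.82e-05). There Grg fell in iNkx2.2 against pMN from 391 ± 213 to 52.97 ± 33.0 CPM (-2.88, adjusted p = 0.000236), HDAC2 by -1.99, p300 by -2.10, H3K4me1 by -1.91 and H3K27ac by -2.99 (57.9 ± 12.1 to 7.24 ± 1.96), while in iTNmut Grg was -0.25 (adjusted p = 0.701), HDAC2 -0.17 (adjusted p = 0.843) and p300 0.14 (adjusted p = 0.843).

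At a site inside Elp4, 28322 bp from Pax6, Grg rose from 21.1 ± 10.6 CPM in pMN to 552 ± 17.5 in iNkx2.2 (log2 4.68, adjusted p = 8.15e-06) and 332 ± 77.2 in iTNmut (3.94, adjusted p = 4.26e-05). HDAC2 there rose in iNkx2.2 (2.02, adjusted p = 0.000274), and in iTNmut p300 (8.02 ± 0.0725 to 60.5 ± 18.1 CPM, log2 2.92) and H3K4me1 (2.08) rose. H3K4me1 was lower with the intact factor than with the mutant (-2.08, adjusted p = 0.00156), and p300 was too (-1.15, adjusted p = 0.0272), though p300 was lost by DESeq2 (adjusted p = 0.0617), on the authors' log2 CPM (0.0593), with column totals (0.0507) and without iNkx2.2 2 (0.198) or iTNmut 1 (0.443). FLAG was 1062 ± 550 CPM in iNkx2.2 and 587 ± 195 in iTNmut (adjusted p = 0.342; 0.00219 without iNkx2.2 2). Grg also rose with both proteins at a site 17278 bp from Irx3, a homeobox gene of progenitors dorsal to pMN (log2 3.13 and 2.02), and at sites inside Tle1 (2.43 and 1.98), 4579 bp from Tle3 (3.82 and 2.94) and inside Tle4 (2.60 and 2.99), genes that encode Groucho proteins. Of their RNAs Tle1 fell with the intact factor, while Tle3 and Tle4 did not pass (0.21, adjusted p = 0.481, or 0.0354 with the replicate block, and -0.17, adjusted p = 0.431).

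**Figure D3:**
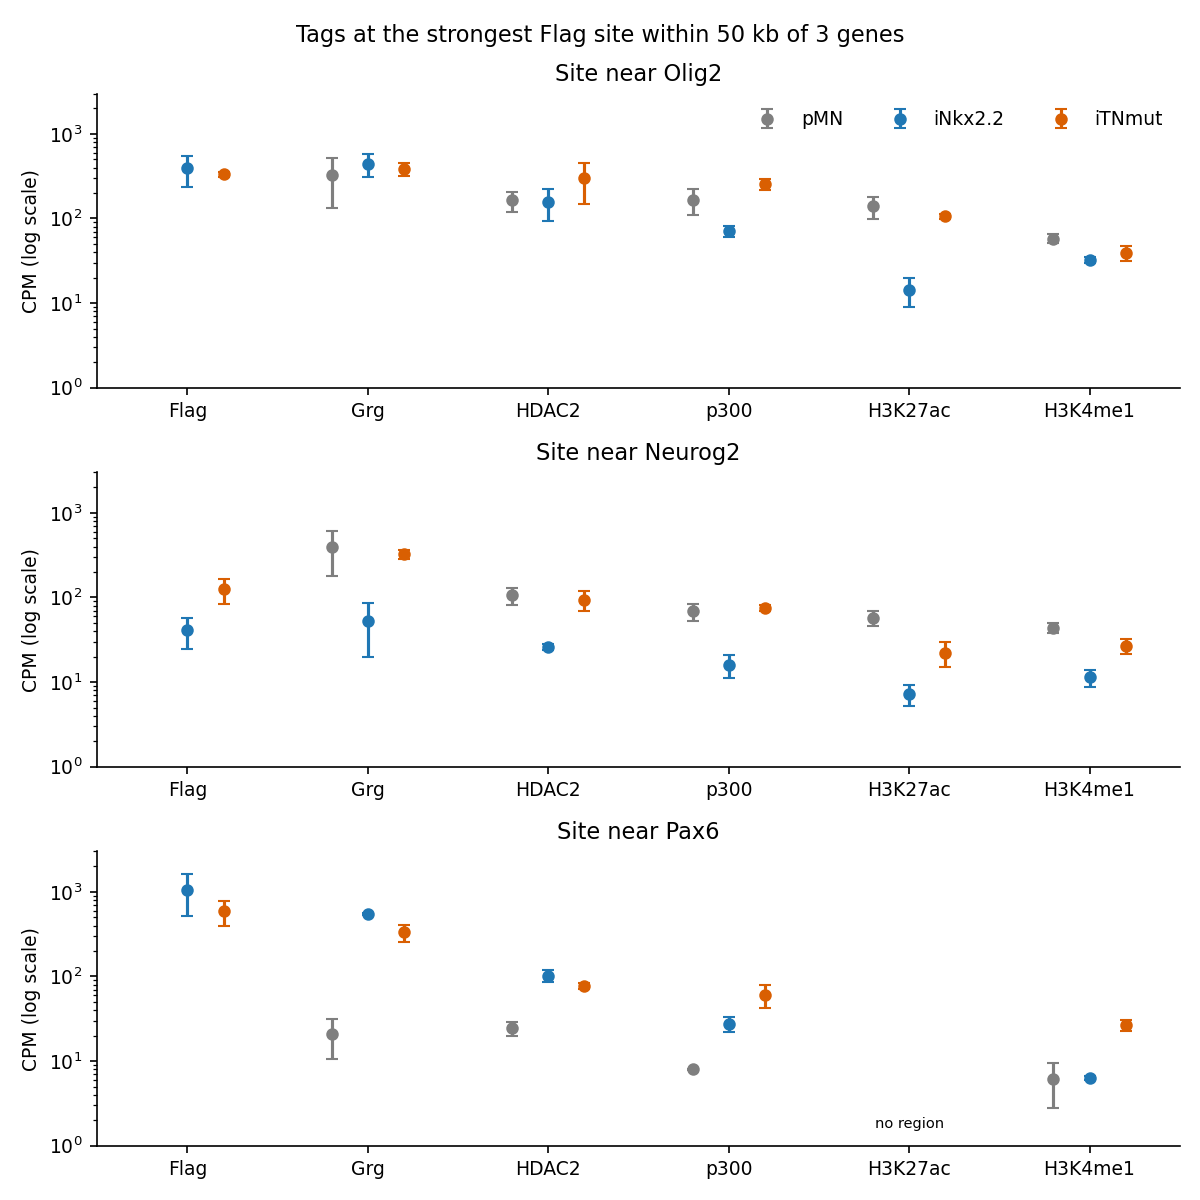
CPM on a log axis (mean ± SD, n = 2) at the strongest FLAG site near Olig2, Neurog2 and Pax6 for FLAG, Grg, HDAC2, p300, H3K27ac and H3K4me1 in each state. Over the Olig2 site H3K27ac was 140 in pMN, 14.3 in iNkx2.2 and 106 in iTNmut.

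The antibodies with single libraries give values without a test. Med1, a Mediator subunit, was 0.13 higher at bound than at other regions in iNkx2.2 against pMN and 0.22 in iTNmut (0.18 for its other library), and -0.11 directly (-0.05). Among regions above the median CPM the iNkx2.2 value reversed to -0.06, and with the 5000 strongest FLAG sites it was 0.62. Sox2, a factor of neural progenitors, gave 0.73, 1.01 and -0.36, but its pMN library came from another study. H3K27me3, the Polycomb mark, gave 0.15, 0.06 and 0.07. Against 10000 random draws of as many regions, these lay at the 100th percentile for Med1 against pMN, at the 0th directly, and at 100, 92.2 and 99.99 for H3K27me3. Each value rests on 1 library per state and holds no spread between cultures.

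Were the regions that lost H3K27ac those used later by motor neurons? Of 1664 regions lower in iNkx2.2, 448 (26.9%, 95% interval 24.8 to 29.1) overlapped a peak in both day 6 motor neuron libraries, and 66.1% of random regions matched for pMN level did (64.1 to 68.2). Of 2358 higher regions, 768 did (32.6%, 30.7 to 34.5), against 31.0% of random ones (29.6 to 32.4; percentile 98.6). With 50% of the region covered the share of lower regions was 11.8%, for which no random share was drawn, and the lower set follows the scaling given above for H3K27ac. Over all H3K27ac regions the share was 57.8%. The intervals cover counting error only.

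Were genes near FLAG sites shifted as a group? Near genes were the 5553 that were nearest to a site and within 50 kb of it, and the 8449 others may still lie within 50 kb of a site. Their medians differed by -0.02 in iNkx2.2 (camera adjusted p = 0.64), 0.00 in iTNmut (adjusted p = 0.914) and -0.02 directly (adjusted p = 0.64). With the 5000 strongest FLAG sites the iNkx2.2 value was -0.08, which passed by unadjusted camera p. More of the near genes were called, in either direction: 7.76% higher and 8.28% lower in iNkx2.2 against 5.95% and 4.72% of the others, and 2.59% and 2.31% against 1.01% and 0.923% in iTNmut.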

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

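Except for endoderm and mesoderm markers, taken up as signs of other cell types, results here were taken up because the change from pMN differed between iNkx2.2 and iTNmut by the direct test or belongs to such a difference. The tests of FLAG sites without a call, of FLAG sites under 0.25, of the transgene level, of the parental lines and of the neural progenitor share were chosen only after the results were seen. Across RNA, 1668 genes differed between the 2 changes. By gene, the log2 difference was -5.119 for Olig2, -5.006 for Pax6, -4.441 for Neurog2, -4.423 for Olig1, -3.143 for Nkx2-9, -2.955 for Gli1, -2.933 for Irx3, -2.872 for Lhx3, -1.03 for Ptch1, -0.8428 for Tle1, 1.244 for Foxa2 and 4.636 for Sim1, which had 114 reads in iNkx2.2 and 3 in iTNmut (ratio 29.4, 95% counting interval 9.82 to 145). For Dll1 it was 0.5123 (adjusted p = 0.0446), which was lost without pMN 3 (0.0519), iNkx2.2 1 (0.166), iTNmut 1 (0.0888), iTNmut 2 (0.116) or iTNmut 3 (0.0957) and with limma on log2 FPKM (0.068). For Nkx6-1 it was 0.9167 (adjusted p = 0.0353), which was lost without iNkx2.2 1 (adjusted p = 0.104), iNkx2.2 3 (0.11), iTNmut 1 (0.0984) or iTNmut 2 (0.11) and with limma on log2 FPKM (0.0817). At Nkx2.2-bound regions the difference was 0.68 for Grg, -0.1785 for H3K27ac, -0.6633 for p300 and -0.1241 for H3K4me1. By camera with an estimated correlation each of these calls was lost (adjusted p = 0.0661, 0.135, 0.182 and 0.135).

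Grg at bound regions, set against other regions, was lower with the TN mutant than with the intact factor, a call lost with an estimated correlation (adjusted p = 0.0661). A single library was excluded as the cause, the lowest value without each being 0.6097. Binding that differs from site to site stayed open: at FLAG sites under 0.25 apart the difference was 0.5154, which met the bound set for the test, but that bound was wrong in using other regions as its base, since their own median was -0.44 while the bound regions' own medians were 1.43, 0.07 and -1.33 at sites with more intact factor, no call and more mutant. A lower transgene level in iTNmut could account for it too, as Nkx2-2 RNA was 0.6387 log2 higher in iNkx2.2. That difference did not pass in the main fit and passed in some alternatives, and the RNA and Grg libraries are not matched. The biological explanation, loss of the Grg contact with the TN domain, was not parted from binding, level and line by these data.

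In iTNmut p300, H3K27ac and H3K4me1 were higher at bound regions, set against other regions, than in pMN, calls that were all lost with an estimated correlation (adjusted p = 0.0616, 0.144 and 0.0616). Sites bound by the mutant alone were tested at sites with no FLAG call, where the smallest of the 3 differences was 0.1685. The bound regions' own medians there were 0.89 for p300, 0.12 for H3K27ac and 0.22 for H3K4me1. Sites called for the mutant were thus not the only source, though a site without a call may still differ in binding. A single library was excluded, the lowest value without each being 0.1525. The parental lines and the absence of doxycycline in pMN remained open: the H3K27ac difference was 0.0001271 in iNkx2.2 (-0.1513 with the 5000 strongest FLAG sites), also induced and also another line, but an effect of the intact factor may hide the same offset.

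Markers of endoderm (1 of 8 called) and mesoderm (3 of 7 called) were lower as lists in iTNmut than in pMN, calls lost with an estimated correlation (adjusted p = 0.566 and 0.229). A single pMN library with more of these transcripts was not the whole source. The median over both lists, -1.693 with all libraries, stayed at -1.159 or below without each (-1.726, -2.004 and -1.159). The endoderm call itself was lost without pMN 1 or without pMN 3, so that list does depend on single pMN libraries. A higher share of neural progenitors in iTNmut could account for it and was left open. iTNmut was also another line than the RNA pMN libraries and had doxycycline, so neither can be parted from the mutant factor here. Neural crest, endothelial and blood markers had a mean of -0.1444 (SD 1.113, n = 10 genes) against -1.335 (SD 1.378, n = 15 genes) for both lists. The difference was 1.191 (permutation p = 0.0329, 100000 resamples of genes). That permutation treats genes as independent and holds no spread between libraries. The estimated correlation between endoderm genes was 0.7037, so its p-value decides nothing here. No biological explanation was tested.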

How the results depend on the processing

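The settings with library totals from peak list headers, the authors' log2 CPM, 500 bp windows and FLAG sites by class were chosen only after the results were seen. Settings of bound regions and of near genes were scored by unadjusted camera p, and those of Med1, Sox2 and H3K27me3 by direction and size alone. Of 261 settings of bound regions 235 stayed the same by these rules, 7 were weaker, 4 stronger, 14 moved and 1 reversed. Of 293 settings of counts 221 stayed within 1.5 times and 72 moved. Of 42 for genes near sites 41 stayed. Named genes kept their call in 5243 of 5682 settings (215 weaker, 224 stronger), lists in 765 of 858 (64, 29) and named regions in 3421 of 3629 (141, 67). Counts per region and spread between replicates limit small changes: with those of the Grg libraries 2.00% of simulated 2-fold changes were recovered.

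By DESeq2 the calls were 874 (RNA, iTNmut against pMN), 2509 (RNA, direct), 4521 (H3K4me1, iTNmut against pMN) and 3573 (H3K4me1, direct). With the replicate block, RNA calls were 5061, 1885 and 5070 (iNkx2.2 against pMN, iTNmut against pMN, direct), and the block changed no other list call beyond those given in the report. It also called further single genes, so counts of list members hold for the fit without it. ChIP replicates, 2 per state, were taken to share numbers only: same-numbered deviations correlated at -0.102 to 0.382 over antibodies and at 0.127 to 0.212 for HDAC2, where the block gave 3105, 1308 and 2848 HDAC2 calls. With limma on log2 FPKM, RNA calls were 1151, 208 and 839. With only the 2 groups compared, HDAC2 in iTNmut against pMN gave 1372 and H3K4me1 directly 8650; on the authors' log2 CPM that HDAC2 count was 424, and with header totals H3K27ac in iNkx2.2 against pMN gave 6853.

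With an estimated correlation 0, 0 and 0 lists passed, and calls at bound regions were lost for HDAC2 in iNkx2.2 (0.3726), H3K27ac in iTNmut (0.1655) and directly (-0.1785), p300 in iNkx2.2 (0.4764) and directly (-0.6633), and H3K4me1 in iNkx2.2 (0.1738) and directly (-0.1241). After adjustment over the 15 tests, Grg directly (adjusted p = 0.0661) and HDAC2 (0.102), p300 (0.0616) and H3K4me1 (0.0616) in iTNmut were lost too by limma camera. With the 5000 strongest FLAG sites, near genes in iNkx2.2 passed at -0.08473, HDAC2 directly at 0.2057 and H3K27ac in iNkx2.2 at -0.1513, all by unadjusted camera p. That setting gave 0.6154, 0.6727 and -0.0736 for Med1, 1.08, 1.096 and -0.1558 for Sox2, and 0.3738 and, directly, 0.2267 for H3K27me3. Among regions above the median CPM, Med1 in iNkx2.2 reversed to -0.0614 and was 0.1151 in iTNmut and -0.2159 directly, and Sox2 was 1.112 in iTNmut and -0.4314 directly. Med1 in iTNmut was 0.2005 with 500 bp windows, and directly -0.07131 in an edgeR fit whose spread came from the 2 iTNmut libraries alone, which is no test of the single iNkx2.2 library. Day 6 overlap was 34.38% with replicate 2 peaks and 11.78% with 50% of the region covered. The cause of these differences was not tested.

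Without each library in turn (a lone library assumed to vary like the other groups), RNA calls spanned 917 to 1926, 246 to 424 and 878 to 1811, FLAG 6067 to 10165, Grg in iTNmut 5599 to 9423 and directly 2383 to 8576, HDAC2 291 to 2382, 48 to 1326 and 223 to 2410, H3K27ac 1907 to 4237, 648 to 2585 and 941 to 3367, p300 638 to 6630, 635 to 6917 and 1555 to 8296, and H3K4me1 5229 to 13885, 2269 to 10038 and 1118 to 8692. HDAC2 at bound regions directly spanned -0.1563 to 0.144. Scaling moved medians by over 0.1 log2 for FLAG (-0.196, column totals), Grg (0.13 in iTNmut with column totals; -0.231 and -0.168 with RLE), H3K27ac (-0.513, -0.18 and -0.333 with header totals), p300 (-0.112 in iTNmut, column totals) and H3K4me1 (-0.176 and -0.234, header totals).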

Other observations

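No test in this part was chosen after its result was seen. The 3 RNA comparisons were set against the other ways of splitting the 6 libraries. Of 10 splits each, the real one included, only the real split gave as many calls and the others gave 0 (iNkx2.2 against pMN, 1 of 10; iTNmut against pMN, 1 of 10; iNkx2.2 against iTNmut, 1 of 10), so the smallest p such splits allow is 0.1. The real splits gave 1631, 368 and 1571 calls, and the highest of the others that part as many replicate pairs gave 0. With so few splits, chance could not be excluded by this test alone.

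The share of H3K27ac tags that fell in regions was 14.6% and 17.7% in the pMN libraries, 11.9% and 10.1% in iNkx2.2 and 13.9% and 13.5% in iTNmut. Sim1 had 3 reads over the iTNmut libraries and 13 over the pMN libraries, a ratio of 0.177 (95% counting interval 0.0324 to 0.645).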
